A study of Sus scrofa with 30 samples.

How the data were processed

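RNA was sequenced from the liver, from subcutaneous and retroperitoneal fat and from the muscles longissimus dorsi and psoas major of 3 transgenic and 3 wild-type pigs, 30 libraries in all. Libraries whose titles share a prefix were taken as coming from the same animal, so the animal is the replicate. The deposited table gives 1 value per gene and library, for 18051 genes, and 0 of its value columns lacked a sample. The values are taken as TPM, since the submitters' processing notes name kallisto 0.44.0 beside STAR 2.6.0c. FPKM cannot be ruled out, because the deposited columns add up to between 26994 and 423019, and the genome build is not given in the sources used here. Of all pairs of libraries 0 were identical, and correlations within a group ran from 0.92 to 0.992.

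Genes keep the identifiers of the table. It names 16164 genes and leaves 1887 unnamed, of which 229 were named from a reference table that holds 13712 of the identifiers, so that 1658 have no symbol. A further count of 1365 genes share a symbol with another gene and are called uncertain where they are named. The 43 gene lists, which cover pathways and cell type markers, have 857 members, of which 794 were matched by symbol and 63 were not. Of those matched, 34 were matched through the reference alone. Where several genes carry a member's symbol, the one with the highest mean level was used.

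Values were analysed in R 4.3.3 with limma 3.58.1 as log2(TPM + 1), as deposited, for genes with a mean of at least 0.5 TPM over the libraries compared. Each tissue was fitted on its 6 libraries with the genotype alone, by a linear model with empirical Bayes moderation and a variance trend, two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The mean over tissues used the mean of the 5 log2 values of each animal. Differences of the genotype effect between the muscles and between the fat depots used the difference between the tissues within each animal, and the tissues themselves were compared over 12 libraries with the animal as a block. For both muscles, both differences of effects and both comparisons of tissues, the moderation as deposited set each gene's variance to the trend over genes. Their limma p-values thus do not measure a gene's own spread between animals. FST was tested by a two-sided exact permutation test. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists tested in the comparison, and their members were counted over all genes and adjusted over the list alone. At the preset correlation camera treats the genes of a list as nearly independent, so its p-values do not measure the spread between animals. Beside camera, the self-contained test fry called 1 list in liver and 0 in the other comparisons as deposited. After scaling it called 1 in liver, 14 between the muscles, 1 between the fat depots and 0 in the others. No member of the Y-linked list was tested.

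Named genes were picked by a rule. For each tissue these were the called genes with a symbol, at least 1 TPM in the higher group and no overlap between the groups, up to 10 per direction by fold change, filled up to 5 by unadjusted p with genes that did not pass. For the other comparisons the numbers were 6 and 3. From each list described, up to 4 members with the smallest unadjusted p and any called member could be named, and from marker lists up to 4 by smallest p or highest level. Some genes picked by this rule are not reported here. The sample groups, tests, lists, this rule and the first set of alternatives were chosen before the data were examined. That set held a pseudocount of 0.1 TPM, no filter on low values, median-of-ratios scaling of the libraries, leaving out each replicate, the replicate number as a block (or none, where the block is in the test) and all 30 libraries in 1 fit. Scaling together with leaving out a library with an outlying scale or with transcripts of another tissue, a variance trend on the expression level for the 2 differences of effects, and leaving out each replicate for FST were added after seeing the data.

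The fits were tested on simulated data in which known genes were changed by 2-fold or 4-fold, with noise drawn independently per gene. As deposited, 4-fold changes were recovered in 88% of genes in liver (10411 genes run), 0% in longissimus dorsi (7113), 0% in psoas major (8894), 35.9% in subcutaneous fat (12891), 57.3% in retroperitoneal fat (12545), 97% in the mean over tissues (12208), 19.1% between the muscles (8027), 94.8% between the fat depots (12730), 0% for the difference of effects between the muscles (8180) and 5.15% for that between the depots (12840). After scaling these shares were 87%, 78.8%, 83.1%, 72.8%, 74%, 97%, 98.9%, 86.5%, 38.9% and 0% in the same order. For 2-fold changes they were 32.3%, 0%, 0%, 0%, 34%, 82%, 0%, 3.16%, 0% and 1.02% as deposited, and 43.8%, 36.8%, 39.8%, 11.3%, 24.5%, 86%, 81.1%, 56.8%, 3.06% and 0% after scaling. Unchanged genes called as deposited numbered 46, 3, 0, 19, 185, 12, 13, 119, 0 and 21, and after scaling 9, 5, 2, 6, 7, 7, 6, 9, 2 and 0. The changed list was found in every comparison and 0 of 19 unchanged lists were called in any. Those lists were drawn at random with independent noise, so this could not test lists whose genes vary together. As deposited, the fits of both muscles and of the difference of effects between them thus recovered 0% of 4-fold changes, so that a gene not called there was not shown to be unchanged.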

Results

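Transcript levels were measured by RNA sequencing in 5 organs of pigs carrying a human follistatin transgene and of wild-type pigs. Follistatin is a secreted protein that binds activins and myostatin, and the study asks how the transgene affects muscle mass, fat deposition and the liver. The liver, subcutaneous and retroperitoneal fat and the muscles longissimus dorsi and psoas major were each taken from 3 transgenic and 3 wild-type animals, described as over 11 months of age, which gave 10 groups of 3 libraries and 30 libraries in all. The table lists 18051 genes in values taken as TPM. The listed values of a library added up to between 26994 and 423019 TPM, and transcripts outside the table were not analysed here. Within an organ the totals differed by 2.26-fold in liver, 5.68-fold in longissimus dorsi, 6.34-fold in psoas major, 2.2-fold in subcutaneous fat and 2.94-fold in retroperitoneal fat. The lowest totals were those of transgenic longissimus dorsi 2 and wild-type psoas major 3. Levels are given as the mean ± SD in TPM over the 3 libraries of a group unless another n is stated. Fold changes are differences on the log2(TPM + 1) scale, which understates the change of genes with low values. Adjusted p-values are those of limma with the Benjamini-Hochberg adjustment. Because the totals differed, each comparison is also given after every library was divided by its median ratio to the others, called scaling below.

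The pig follistatin gene, FST (ENSSSCG00000016892), was listed in all 30 libraries, and its level did not separate the genotypes in any organ. In liver FST was at 0.51, 0.73 and 0.40 TPM in the transgenic libraries and at 0.04, 3.6 and 1.12 TPM in the wild-type libraries. In longissimus dorsi FST was at 1.07, 0.25 and 1.27 TPM in transgenic and at 0.97, 0.52 and 0.70 TPM in wild-type libraries. In psoas major it was at 1.06, 1.12 and 0.82 TPM against 0.96, 0.66 and 0.23 TPM. Levels were higher in fat, at 8.61, 13.8 and 3.88 TPM in transgenic and 15.4, 10.2 and 12.6 TPM in wild-type subcutaneous fat, and at 5.14, 13.3 and 11.0 TPM against 2.97, 6.15 and 16.3 TPM in retroperitoneal fat. The log2 differences of transgenic from wild-type were -0.49 in liver, 0.07 in longissimus dorsi, 0.33 in psoas major, -0.61 in subcutaneous fat and 0.37 in retroperitoneal fat, and after scaling those of longissimus dorsi and retroperitoneal fat were -0.06 and -0.22. Two-sided exact permutation tests gave p = 0.6, 0.8, 0.2, 0.3 and 0.7 in the same order, or 0.7, 0.8, 0.2, 0.2 and 0.8 after scaling, and 0.1 is the smallest p that 3 animals against 3 can give. The table has no separate entry for the human transgene, so these values test the labels only as far as reads of the transgene were assigned to the pig gene. Myostatin, MSTN (ENSSSCG00000016047), which limits muscle growth, was at 1.85 ± 1.57 against 1.13 ± 0.194 TPM in longissimus dorsi (exact permutation p = 0.7) and at 2.28 ± 1.21 against 1.07 ± 0.805 TPM in psoas major (exact permutation p = 0.3). After scaling its log2 differences were 0.08 and 0.51, and the exact permutation p was 0.6 and 0.1.

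The liver comparison asks how the organ's metabolism differed in the transgenic animals. Transcripts of the skeletal muscle contractile apparatus were higher in the transgenic liver libraries. Over 42 genes abundant in muscle and low in wild-type liver, the median difference was 0.276% of the muscle level. Small amounts of muscle RNA in these libraries could account for the rise, as described below, and expression by the liver was not shown. ACTA1 (ENSSSCG00000010190), skeletal muscle actin, was at 7.70 ± 0.839 TPM against 0.883 ± 0.263 TPM, a log2 fold change of 2.21 (SE 0.231, adjusted p = 1.71e-05). TNNC1 (ENSSSCG00000011441), a troponin C of slow and cardiac muscle, was at 2.88 ± 0.303 against 0.207 ± 0.071 TPM, and MYLPF (ENSSSCG00000007799), the fast myosin regulatory light chain, at 7.89 ± 1.18 against 1.88 ± 0.562 TPM. MYL1, MYH2, TNNT3, TNNC2 and TCAP rose as well, with log2 fold changes of 1.47, 1.32, 1.18, 1.18 and 1.16. Of the 9 measured skeletal muscle markers 8 rose, both over all genes and adjusted over the list alone, with a median log2 fold change of 1.18 (camera adjusted p = 5.16e-95, and adjusted p = 0.019 with an estimated correlation). After scaling the median was 1.52 and all 9 were positive, and the list no longer passed with an estimated correlation (camera adjusted p = 2.26e-41, adjusted p = 0.0547 with an estimated correlation).

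**Figure D1:**
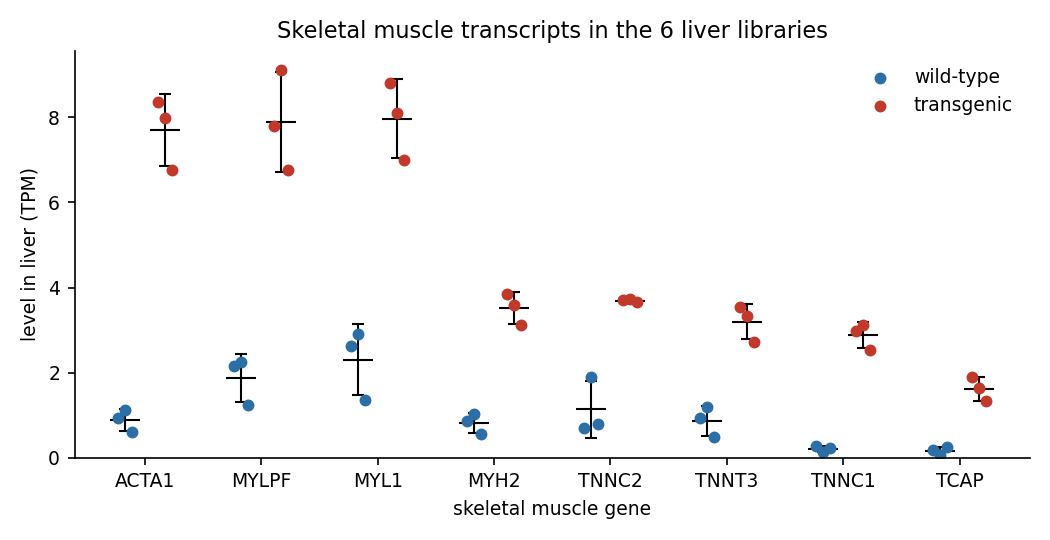
Level in TPM (vertical axis) of 8 skeletal muscle genes (horizontal axis) in the 6 liver libraries. Points are libraries, with wild-type in blue and transgenic in red, and bars give the mean and SD of 3. In each gene every transgenic library lies above every wild-type library.

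Genes of the sterol pathway and of red blood cells had lower values in transgenic liver as deposited. Of 23 measured cholesterol synthesis genes 4 fell, and 16 were lower when adjusted over the list alone, or 2 after scaling. The 4 were TM7SF2 at 7.41 ± 0.786 against 19.6 ± 3.63 TPM, SC5D at 15.3 ± 3.32 against 37.8 ± 7.69 TPM, DHCR7 at 3.13 ± 0.625 against 8.22 ± 3.03 TPM and SQLE, squalene epoxidase, at 5.003 ± 0.886 against 14.7 ± 8.06 TPM. The list's median log2 fold change was -0.91, where that of all genes was -0.39, and after scaling it was -0.42 with 22 of 23 genes negative (camera adjusted p = 1.91e-08, adjusted p = 0.797 with an estimated correlation). Of 4 measured erythroid genes, HBA2, an alpha globin, fell from 50.02 ± 23.9 in wild-type to 12.5 ± 6.13 TPM and ALAS2, the erythroid enzyme that starts haem synthesis, from 8.11 ± 4.004 to 1.96 ± 0.860 TPM. Adjusted over the list alone 3 were lower, or 0 after scaling, and the list's median was -1.66, or -1.19 after scaling (camera adjusted p = 0.000253, adjusted p = 0.797 with an estimated correlation). FASN, fatty acid synthase, fell from 1.74 ± 0.271 to 0.473 ± 0.0982 TPM (adjusted p = 0.013). None of these sterol, erythroid and lipid genes passed the threshold over all genes after scaling.

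The largest falls among single liver genes were those of GALP (ENSSSCG00000003318), a galanin-like peptide, at 0.563 ± 0.312 against 26.3 ± 30.2 TPM, and TECTB (ENSSSCG00000010632), beta-tectorin, at 2.45 ± 1.86 against 23.0 ± 10.2 TPM. MBL2, mannose-binding lectin, was lower at 58.1 ± 18.3 against 310.2 ± 198 TPM and HRG, histidine-rich glycoprotein, at 223.6 ± 79.7 against 769 ± 343.8 TPM. GABARAPL1, an autophagy protein, was at 8.43 ± 1.18 against 36.8 ± 21.3 TPM and AKAIN1 at 0.313 ± 0.272 against 3.66 ± 2.41 TPM. MT-ATP6 and HLA-C (ENSSSCG00000001229) also fell, by 1.84 and 1.75 on the log2 scale, but have symbols that 4 and 5 entries of the table carry and are uncertain. None of these lower genes passed after scaling, where the log2 fold changes of GALP and TECTB were -3.19 and -2.37. LUZP2 rose, at 1.70 ± 0.395 against 0.00667 ± 0.0115 TPM (adjusted p = 3.51e-05), and stayed past the threshold after scaling. MT-ATP8, a mitochondrially encoded ATP synthase subunit, was at 21.9, 57.5 and 1.25 TPM in the transgenic livers and listed at 0 in the 3 wild-type livers (adjusted p = 0.00309, and 0.395 after scaling).

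Of 10456 genes tested in liver, 117 changed, 29 higher and 88 lower, and after scaling 39 changed, 32 higher and 7 lower, with 33 called both ways (26 higher and 7 lower). The groups did not overlap in 114 of the 117 called genes, nor in 43.6% of all tested genes, where chance gives 10%. The median ratios used for scaling separated the genotypes too, at 0.81, 0.85 and 0.835 in transgenic and 1.06, 1.63 and 1.04 in wild-type livers. A difference in library scale can thus separate the groups in many genes as deposited, apart from any effect on single genes. Of the 117, 22 have no symbol and 7 have a group at 0. Besides those above, heat shock genes, acute phase genes, smooth muscle and pericyte markers, adipocyte markers and B and plasma cell markers were higher than other genes by camera (adjusted p = 4.36e-05, 0.000465, 4.36e-05, 0.0242 and 0.0433), and with an estimated correlation these gave adjusted p = 0.908, 0.908, 0.797, 0.797 and 0.908. The medians of these lists were negative as deposited, at -0.25 for heat shock genes, and positive after scaling, at 0.23, when only those of heat shock genes and smooth muscle and pericyte markers passed among these 5. The count was 319 without wild-type liver 1, 33 without wild-type liver 2 and 941 without wild-type liver 3, and with no filter on low values it was 23. In the simulation this fit called 46 unchanged genes as deposited and 9 after scaling, so a part of the 117 may be false calls.

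The longissimus dorsi, a back muscle, was compared to ask how the transgene affects skeletal muscle. A gene that shares the symbol UQCRH (ENSSSCG00000035894), annotated as the hinge subunit of mitochondrial complex III, rose from 0.227 ± 0.197 to 7.58 ± 4.24 TPM (log2 fold change 2.66, SE 0.595, adjusted p = 0.02, and 0.00117 after scaling). It is uncertain, since 2 genes carry this symbol and reads could be split between them. MT-ATP8 was at 87.7, 6.43 and 0.00 TPM in transgenic and at 0.00, 0.40 and 0.00 TPM in wild-type libraries, so that the groups overlapped (adjusted p = 0.00596, and 0.999 after scaling). After scaling, NREP (ENSSSCG00000034993), a neuronal regeneration related protein, and ARG2 (ENSSSCG00000002294), the mitochondrial arginase, passed the threshold with log2 fold changes of -2.06 and -2.29. NREP was at 2.55 ± 1.71 against 10.6 ± 1.09 TPM and ARG2 at 0.723 ± 0.379 against 7.44 ± 3.55 TPM, and as deposited their adjusted p-values were 1 and 0.341. Several further genes had separate groups and did not pass. MYH8, the perinatal myosin heavy chain, was at 2.67 ± 1.52 against 0.553 ± 0.300 TPM, PVALB, the calcium buffer parvalbumin of fast fibres, at 0.563 ± 0.378 against 2.54 ± 1.05 TPM, THBS2 at 0.333 ± 0.196 against 1.66 ± 0.640 TPM and ASNS, asparagine synthetase, at 2.06 ± 1.26 against 4.47 ± 1.91 TPM. HLA-DRB1 (ENSSSCG00000031336), which shares its symbol and is uncertain, FBLN1 and AC007998.2 also had higher transgenic values without passing, with log2 differences of 0.63, 0.22 and 0.80.

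No member of any list passed the threshold in longissimus dorsi. Fast fibre genes lay below other genes, with a median of -0.05 where all genes had 0.17 (camera adjusted p = 2.94e-06), and so did glycolysis and glycogen genes with a median of -0.02 (adjusted p = 7.6e-05). Extracellular matrix genes and skeletal muscle markers (adjusted p = 0.000124 for each), interferon response genes (adjusted p = 0.000443), oxidative phosphorylation genes (adjusted p = 0.000496) and hepatocyte markers (adjusted p = 1.29e-06) were lower too. Macrophage markers were higher than other genes, with a median of 0.28 (adjusted p = 0.00945). All 8 lists passed after scaling as well, but oxidative phosphorylation and macrophage markers did not when transgenic longissimus dorsi 2 was also left out, an alternative added after seeing the data (adjusted p = 0.24 and 0.15). All 8 had adjusted p = 0.931 with an estimated correlation. Oxidative phosphorylation genes had a median of 0.02 as deposited and of -0.12 after scaling, when 37 of 49 were negative.

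Of 7090 genes tested in longissimus dorsi 8 changed, 6 higher and 2 lower, and 6 of them have no symbol and 5 have a group at 0. After scaling 3 changed, 1 higher and 2 lower, and 1 was called both ways. The groups did not overlap in 4 of the 8, nor in 0.24% of tested genes, where chance gives 10%. The count was 5725 without transgenic longissimus dorsi 2, 4 without transgenic 1, 1 without transgenic 3 and 0 without any one of the 3 wild-type libraries, and with no filter on low values it was 0.

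In psoas major, a loin muscle, the same question was asked. Genes of mitochondrial oxidative phosphorylation were lower than other genes in transgenic animals. Their median log2 fold change was -0.19, where all genes had 0.24, and after scaling it was -0.62 with all 49 genes negative. None of the 49 passed over all genes, but after scaling 31 were lower when adjusted over the list alone. The complex I subunit NDUFS7, at 21.2 ± 8.76 against 38.0 ± 27.5 TPM, and NDUFA4, a subunit of cytochrome c oxidase, at 80.8 ± 40.5 against 137.6 ± 113 TPM, are examples whose libraries overlapped as deposited. Camera gave an adjusted p of 4.5e-10 for the list, and adjusted p = 0.997 with an estimated correlation. Interferon response genes were also lower, with a median of -0.08 or -0.22 after scaling (camera adjusted p = 6.93e-10), as in IFI6 at 2.26 ± 0.562 against 9.13 ± 7.46 TPM. Erythroid markers were lower, and heat shock genes, with a median of 0.68, and hepatocyte markers, with 0.59, were higher (camera adjusted p = 0.0039 for each), and all 4 had adjusted p = 0.997 with an estimated correlation. The erythroid and hepatocyte lists did not pass after scaling. When wild-type psoas major 3 was also left out, an alternative added after seeing the data, the hepatocyte list passed (camera adjusted p = 4.77e-09) and the heat shock list did not (0.0794). The follistatin, activin and myostatin list had 12 measured genes and a median of 0.43 (camera adjusted p = 0.109), and after scaling its median was 0.19 (camera adjusted p = 0.0176, adjusted p = 0.743 with an estimated correlation).

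Of single genes in psoas major, the UQCRH gene ENSSSCG00000035894 rose from 0.490 ± 0.234 to 17.0 ± 3.93 TPM (log2 fold change 3.58, SE 0.749, adjusted p = 0.00508, and 0.181 after scaling). MT-ATP8 was at 280.5, 152.5 and 1.28 TPM in transgenic and at 0.91, 1.23 and 0.61 TPM in wild-type libraries (adjusted p = 0.00181, and 0.318 after scaling). The gene ENSSSCG00000032862, which has no symbol, rose from 0.570 ± 0.987 to 17.8 ± 6.76 TPM (adjusted p = 0.00302, and 0.0344 after scaling), and was named because it completes the 3 called genes. RBP7, a retinol-binding protein, passed after scaling with a log2 fold change of -0.73 (adjusted p = 0.0455), and was chosen after its values were seen. Genes with separate groups that did not pass included NFIL3, a leucine zipper repressor, at 4.90 ± 4.85 against 0.613 ± 0.470 TPM, CXXC4 at 2.86 ± 1.16 against 14.9 ± 13.0 TPM, THBS2 at 0.323 ± 0.0231 against 1.33 ± 0.797 TPM and HIST1H4L at 2.23 ± 0.521 against 11.0 ± 9.72 TPM. SPTY2D1-AS1, PON3 and OTOR, which shares its symbol with another gene and is uncertain, did not pass either, with log2 differences of 0.78, -0.62 and 1.0.

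Of 8877 genes tested in psoas major 3 changed, all higher, and 55 had an unadjusted p under 0.05. After scaling 2 changed, 1 higher and 1 lower, 1157 had an unadjusted p under 0.05, and 1 gene was called both ways. The groups did not overlap in the 3 called genes, nor in 1.13% of tested genes, where chance gives 10%. The count was 0 without transgenic 1, transgenic 2 or wild-type 2, 14 without wild-type 1 and 22 without wild-type psoas major 3, and with no filter on low values it was 0.

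**Figure D2:**
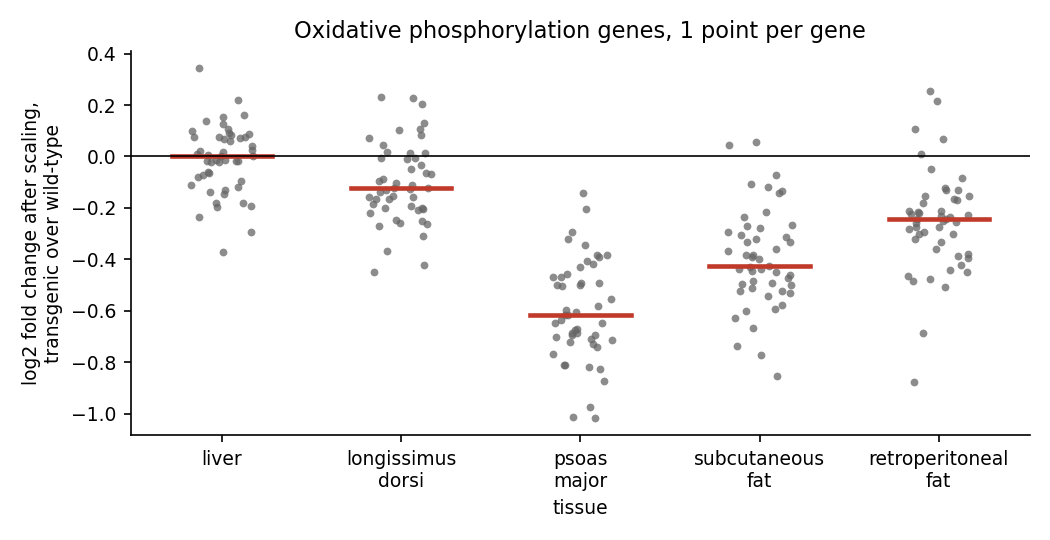
Log2 fold change after scaling, transgenic over wild-type (vertical axis), of the 49 oxidative phosphorylation genes in each of the 5 tissues (horizontal axis). Points are genes and red lines are medians, which were -0.62 in psoas major and -0.43 in subcutaneous fat. As deposited the medians of longissimus dorsi and retroperitoneal fat were positive, at 0.02 and 0.38.

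The subcutaneous fat comparison asks how the transgene affects fat storage. Genes of adipocyte identity, fatty acid oxidation, lipid synthesis and oxidative phosphorylation were lower than other genes in transgenic subcutaneous fat, though no single gene passed the threshold. Of 19 adipocyte identity genes 2 were lower when adjusted over the list alone, PCK1, which makes glycerol phosphate for triglycerides in fat, at 8.83 ± 4.64 against 43.6 ± 34.3 TPM and LPL, lipoprotein lipase, at 118.7 ± 36.1 against 343.4 ± 109 TPM. The list's median log2 fold change was -0.76, or -0.47 after scaling, where that of all genes was -0.23 (camera adjusted p = 1.08e-07, adjusted p = 0.602 with an estimated correlation). Of 26 fatty acid oxidation genes 1 was lower adjusted over the list alone, ECI1 at 5.83 ± 1.05 against 18.9 ± 4.38 TPM, and the median was -0.73, or -0.44 after scaling (camera adjusted p = 3.97e-07). Of 22 fatty acid and triglyceride synthesis genes 1 was, ME1, malic enzyme, at 6.76 ± 1.51 against 24.3 ± 4.34 TPM (median -0.66, camera adjusted p = 7.9e-05). After scaling 0 adipocyte identity, 0 fatty acid oxidation and 2 synthesis genes were lower adjusted over the list alone. The 49 oxidative phosphorylation genes had a median of -0.69, and 47 were negative after scaling (camera adjusted p = 1.42e-09). These 3 lists also had adjusted p = 0.602 with an estimated correlation.

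Other lists that were lower in transgenic subcutaneous fat were extracellular matrix genes, with a median of -0.86 and TNC, tenascin C, lower adjusted over the list alone at 2.81 ± 1.75 against 11.6 ± 3.26 TPM (camera adjusted p = 1.32e-06), interferon response genes (1.84e-05), thermogenic genes (0.000643), cytosolic ribosomal proteins (0.00117), adipocyte markers (0.00146), cholesterol synthesis (0.00298), macrophage markers (0.00629), erythroid markers (0.0294) and lipolysis genes (0.0295). Markers of other tissues differed between the groups as well. Hepatocyte markers had a median of -2.04 with 8 of 14 lower adjusted over the list alone, or 0 after scaling, as for the extracellular matrix genes (camera adjusted p = 1.9e-10), and skeletal muscle markers a median of -1.61 (0.000643). Wild-type subcutaneous fat 2 held most of this difference, with ALB, serum albumin, at 1433 TPM and ACTA1 at 1049 TPM, where the other 5 libraries had at most 111.4 and 34.3 TPM. Genes abundant in muscle and low in fat were at a median of 19.5% of their muscle level in it, and at most 1.06% in the other fat libraries. Keratinocyte markers were higher in transgenic fat, with a median of 1.87 (1.54e-09), and KRT5 was at 73.6 TPM in transgenic subcutaneous fat 2 and at most 1.39 TPM elsewhere. Mesothelial markers (median 1.12, 6.43e-12), T and NK cell markers (0.00415) and Schwann cell markers (0.0236) were higher too. With an estimated correlation the adjusted p of all these lists lay between adjusted p = 0.431 and adjusted p = 0.73, and the erythroid and Schwann cell lists did not pass after scaling.

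Single genes with separate groups in subcutaneous fat did not pass. BMP5, a bone morphogenetic protein, was at 1.01 ± 0.194 against 6.92 ± 0.335 TPM (log2 difference -1.98, SE 0.301, adjusted p = 0.0714, and 0.201 after scaling), and PON3, a lactonase, at 4.99 ± 1.78 against 38.9 ± 17.3 TPM (adjusted p = 0.0714). FCN1 and OTOR, which share their symbols and are uncertain, had log2 differences of -2.14 and -1.98. RPL39L, likewise uncertain, was listed at 0 in the 3 transgenic libraries and at 2.33, 2.06 and 4.86 TPM in the wild-type ones (adjusted p = 0.0714). The UQCRH gene ENSSSCG00000035894 was at 3.24, 2.86 and 0.39 TPM in the transgenic libraries and listed at 0 in the 3 wild-type ones (adjusted p = 0.788). IGHV3-38, S100A2, CST6 and AC233755.2 had log2 differences of 1.64, 1.43, 1.32 and 1.47, and AC233755.2 is uncertain as well.

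Limma called 0 of 12916 genes tested in subcutaneous fat, as deposited and after scaling, and 486 had an unadjusted p under 0.05, 78 higher and 408 lower, or 610 after scaling. Of 30 lists 19 passed, 4 higher and 15 lower, and after scaling 17 passed, or 10 when wild-type subcutaneous fat 2 was also left out, an alternative added after seeing the data. Oxidative phosphorylation, fatty acid oxidation and adipocyte identity genes stayed lower then (camera adjusted p = 4.51e-11, 2.96e-07 and 1.77e-05). The lists of lipid synthesis, cholesterol synthesis, interferon response, lipolysis, T and NK cells, hepatocytes and skeletal muscle no longer passed (0.121, 0.0774, 0.114, 0.0933, 0.0949, 0.168 and 0.0933). The count of genes was 294 without transgenic 1, 23 without wild-type 2, 6 without transgenic 3, 2 without wild-type 3 and 1 without wild-type 1. With a pseudocount of 0.1 TPM it was 7.

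Retroperitoneal fat was compared for the same question in an internal depot. Genes of T cells, hepatocytes, the immediate early response and inflammation were higher in transgenic retroperitoneal fat. With scaling and without transgenic retroperitoneal fat 1, an alternative added after seeing the data, the immediate early list still passed. The T and NK cell, hepatocyte and inflammation lists did not (camera adjusted p = 0.0905, 0.406 and 0.337). CD3D, a subunit of the T cell receptor complex, rose, at 10.1, 3.74 and 10.1 TPM in transgenic and 0.55, 0.89 and 1.06 TPM in wild-type libraries (log2 fold change 2.2, SE 0.340, adjusted p = 0.00091, and 0.352 after scaling). GZMK, a granzyme, rose as well, at 1.02 ± 0.127 against 0.0933 ± 0.0451 TPM (adjusted p = 0.0469). Of 15 T and NK cell markers these 2 passed over all genes and 10 adjusted over the list alone, with a median of 0.71 where all genes had 0.53 (camera adjusted p = 2.62e-06). Of 21 immediate early genes 5 were higher adjusted over the list alone, among them JUNB at 25.7 ± 12.5 against 9.37 ± 6.41 TPM, and the median was 1.03, with all 21 positive after scaling (camera adjusted p = 0.0008). Of 22 inflammation genes 7 were, among them the chemokines CXCL10 at 6.73 ± 4.15 against 1.34 ± 0.572 TPM and CCL2 at 50.8 ± 15.2 against 17.5 ± 14.2 TPM (camera adjusted p = 0.0122). Of 15 cell cycle genes PCLAF rose, at 1.68 ± 0.558 against 0.243 ± 0.220 TPM, and 5 were higher adjusted over the list alone (camera adjusted p = 0.0087). Macrophage markers were higher than other genes with a median of 0.86 and 0 members past (camera adjusted p = 0.01). All of these lists had adjusted p = 0.815 with an estimated correlation. After scaling the members higher adjusted over the list alone were 2 T and NK cell, 0 immediate early, 0 inflammation and 1 cell cycle genes.

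Hepatocyte markers differed between the groups in retroperitoneal fat too: all 13 were higher adjusted over the list alone and 0 over all genes, with a median of 1.45 (camera adjusted p = 2.62e-06, adjusted p = 0.815 with an estimated correlation). Genes abundant in liver and low in fat did not follow the genotype. Their median share of the liver level was 1.44%, 0.499% and 0.0845% in transgenic and 0.0944%, 0.143% and 0.302% in wild-type libraries. ALB was at 534.0, 251.1 and 21.0 TPM in transgenic and at 10.4, 35.5 and 72.1 TPM in wild-type libraries, so that the groups overlapped. Single genes that rose included a liver product, BHMT, a methyltransferase of methionine synthesis, at 11.9 ± 6.09 against 1.21 ± 1.08 TPM (log2 fold change 2.54, adjusted p = 0.000901). Complement genes C3, at 48.3 ± 38.1 against 7.47 ± 4.41 TPM, and CFB, at 9.63 ± 4.47 against 1.45 ± 1.09 TPM, and the matrix protein gene THBS4, at 12.5 ± 6.83 against 1.43 ± 1.91 TPM, rose as well. Skeletal muscle markers (4 higher adjusted over the list alone, camera adjusted p = 0.0417, adjusted p = 0.825 with an estimated correlation) and adrenal and kidney markers (3 of 3 adjusted over the list alone, camera adjusted p = 0.0104, adjusted p = 0.815 with an estimated correlation) were higher too. After scaling 0 members of the hepatocyte, skeletal muscle and adrenal and kidney lists were higher adjusted over the list alone. HIST1H3B and HLA-C (ENSSSCG00000001231) rose by log2 2.29 and 2.56 and are uncertain.

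Relative to other genes, cytosolic ribosomal proteins, fatty acid and triglyceride synthesis, oxidative phosphorylation, fatty acid oxidation and adipocyte identity genes were lower in transgenic retroperitoneal fat. Their medians were 0.39, 0.20, 0.38, 0.31 and 0.41 as deposited, below the 0.53 of all genes, and -0.28, -0.29, -0.24, -0.36 and -0.26 after scaling (camera adjusted p = 2.62e-06, 1.36e-05, 0.000109, 0.00101 and 0.01). With an estimated correlation these gave adjusted p = 0.815, and 0.825 for oxidative phosphorylation. In the lipid synthesis list the desaturases FADS1 and FADS2 were higher adjusted over the list alone, against the list's direction, but after scaling 0 were higher and 3 lower. Erythroid markers were lower, with a median of -0.01 and a mean of 0.08 (camera adjusted p = 0.00461, adjusted p = 0.815 with an estimated correlation). Extracellular matrix genes were lower by camera (adjusted p = 0.0479, adjusted p = 0.834 with an estimated correlation) although their median of 0.59 lay above that of all genes. Neither of these 2 lists passed after scaling. PIK3C2G (ENSSSCG00000000591), a lipid kinase, fell from 2.54 ± 0.644 to 0.207 ± 0.125 TPM (log2 fold change -1.54, adjusted p = 0.00132, and 0.124 after scaling). GYS2, the liver glycogen synthase, was at 4.68 ± 1.88 against 22 ± 12.6 TPM and did not pass (adjusted p = 0.0508). TTC37 and TPSB2, which share their symbols and are uncertain, fell by 1.36 and 1.17 on the log2 scale, and GNG14 was listed at 0 in the 3 transgenic libraries and at 0.39, 1.18 and 1.53 TPM in wild-type ones (adjusted p = 0.041).

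Of 12585 genes tested in retroperitoneal fat 80 changed, 74 higher and 6 lower, of which 30 have no symbol and 12 have a group at 0. On simulated data this fit called 185 unchanged genes as deposited, so many of the 80 may be false calls. After scaling the only gene called was UQCRH ENSSSCG00000035894, which was also called as deposited (adjusted p = 9.38e-08, and 0.000493 after scaling), at 6.43, 14.5 and 12.8 TPM in transgenic libraries and listed at 0 in wild-type ones, and 874 genes had an unadjusted p under 0.05 by limma after scaling. MT-ATP8 was at 48.4, 160.8 and 1.26 TPM in transgenic and listed at 0 in wild-type libraries (adjusted p = 0.00164, and 0.553 after scaling). The groups did not overlap in 75 of the 80, nor in 26.8% of tested genes, where chance gives 10%. Of 30 lists 15 passed, 8 higher and 7 lower, and after scaling 13 passed, 8 higher and 5 lower. When transgenic retroperitoneal fat 1 was also left out, an alternative added after seeing the data, 8 passed, 3 higher and 5 lower. The T and NK cell, hepatocyte, macrophage, inflammation, skeletal muscle and adipocyte identity lists no longer passed then (camera adjusted p = 0.0905, 0.406, 0.941, 0.337, 0.953 and 0.0974), and the immediate early, cell cycle and adrenal and kidney lists stayed higher. The count of genes was 1305 without transgenic 1, 190 without transgenic 2, 262 without transgenic 3, 3 without wild-type 1, 164 without wild-type 2 and 319 without wild-type 3, and 3 with no filter on low values.

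The mean over the 5 tissues of each animal asks which genes differed between the genotypes throughout the body. The UQCRH gene ENSSSCG00000035894 rose, with a log2 fold change of 2.70 (SE 0.095, adjusted p = 3.24e-07, and 0.00176 after scaling) and after scaling higher in 15 of 15 transgenic libraries than in any wild-type library of the same tissue. It was called in 4 of the 5 tissues, and in 3 after scaling, while the other UQCRH gene, ENSSSCG00000003903, was called in 0. MT-ATP8 was called in 4 tissues, and in 0 after scaling. Genes that did not pass included GYS2, BMP5, AC233755.2, HLA-C (ENSSSCG00000001231) and TTC37, with log2 differences of -0.86, -0.57, 0.68, 1.16 and -1.11. Of these AC233755.2, HLA-C and TTC37 share their symbols and are uncertain. Of 49 oxidative phosphorylation genes 48 were negative after scaling, with a median of -0.28, and 31 were lower adjusted over the list alone; as deposited the median was -0.19, where all genes had 0.05, and 0 were (camera adjusted p = 2.28e-14, adjusted p = 0.721 with an estimated correlation).

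**Figure D3:**
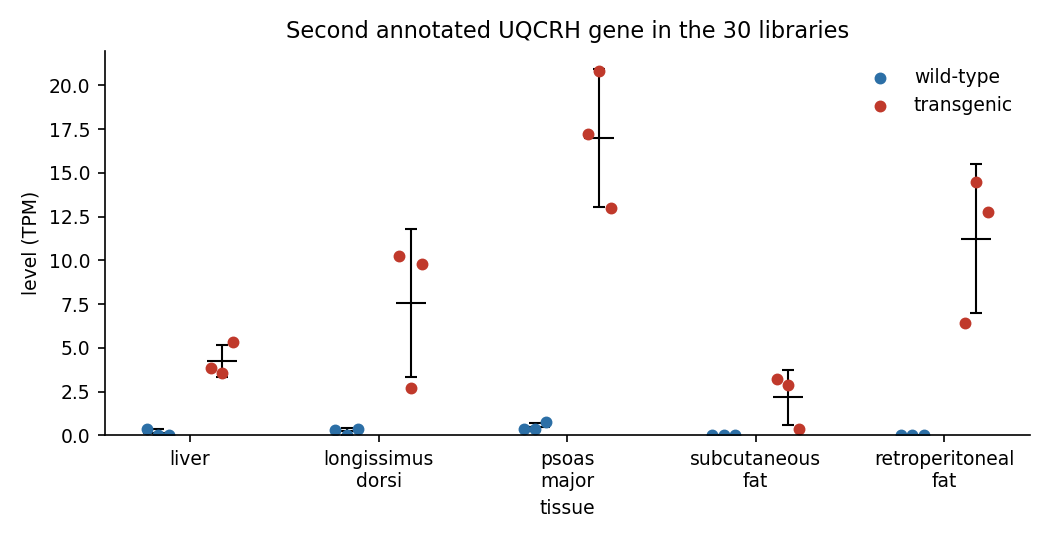
Level in TPM (vertical axis) of the UQCRH gene ENSSSCG00000035894 in each of the 5 tissues (horizontal axis). Points are libraries, with wild-type in blue and transgenic in red, and bars give the mean and SD of 3. Each transgenic library lies above the wild-type libraries of its tissue.

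Averaged over the tissues, fatty acid and triglyceride synthesis genes and cholesterol synthesis genes were lower than other genes, with medians of -0.14 and -0.10 (camera adjusted p = 3.53e-07 for each). Interferon response genes (5.05e-07), extracellular matrix genes (0.000573), fatty acid oxidation genes (0.00241), hepatocyte markers (0.00512), cytosolic ribosomal proteins (0.00552) and erythroid markers (1.38e-05) were lower too, and T and NK cell markers (0.00498) and heat shock genes (0.0208) were higher. Erythroid markers had a median of -0.59, and ALAS2 and HBA2 were lower adjusted over the list alone, or 0 genes after scaling. With an estimated correlation these gave adjusted p = 0.721 or adjusted p = 0.878, and hepatocyte markers did not pass after scaling. Of 12183 genes tested 1 changed, and 677 had an unadjusted p under 0.05, or 1128 after scaling. The count was 13 without wild-type 1, 4 without transgenic 3, 3 without wild-type 3, and 2 without transgenic 1 or wild-type 2, and 3 with a pseudocount of 0.1 TPM.

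The 2 muscles were compared within the 6 animals to ask how they differ in fibre type. Genes of slow fibres and of fatty acid oxidation were lower in longissimus dorsi than in psoas major. MYL3, the slow myosin light chain, was at 33.4 ± 19.8 TPM in longissimus dorsi and 371.2 ± 348 TPM in psoas major (n = 6 libraries each, log2 fold change -3.22, SE 0.729, adjusted p = 0.00257), lower in 6 of 6 animals. PLN, phospholamban, which restrains the calcium pump of slow fibres, was at 378.4 ± 245.5 against 3048 ± 1940 TPM, MYL2 at 55.6 ± 36.0 against 487.6 ± 438.9 TPM and MYOZ2 at 7.56 ± 7.58 against 69.6 ± 64.0 TPM. FABP3, which carries fatty acids in oxidative muscle but is uncertain since it shares its symbol, was at 3.48 ± 2.10 against 101.3 ± 84.8 TPM (adjusted p = 5.25e-07). Of 16 slow fibre genes 11 were lower over all genes and all 16 adjusted over the list alone, or 15 after scaling, with a median of -2.40, or -1.60 after scaling (camera adjusted p = 1.06e-31, adjusted p = 0.336 with an estimated correlation). Of 27 fatty acid oxidation genes 6 were lower and 14 adjusted over the list alone, or 20 after scaling (median -1.32, or -0.69 after scaling, camera adjusted p = 6.06e-10, adjusted p = 0.745 with an estimated correlation). The 6 were CPT2, PPARGC1A, ACADVL, HADHB, CPT1B and PPARA, and CPT1B, the muscle enzyme that lets fatty acids into mitochondria, was at 3.6 ± 2.35 against 19.3 ± 14.3 TPM.

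Fast fibre and glycolytic genes were higher in longissimus dorsi relative to other genes. The 17 fast fibre genes had a median of 0.10 and the 23 glycolysis and glycogen genes one of 0.20, where all genes had -0.45, with 0 past the threshold as deposited (camera adjusted p = 2.21e-13 and 1.86e-14, adjusted p = 0.673 for both with an estimated correlation). After scaling the medians were 0.84 and 0.99, and 12 and 18 genes passed, among them MYH4, a fast myosin heavy chain, at 1029 ± 625 against 570.4 ± 414 TPM as deposited. IGFN1 (ENSSSCG00000036948), a sarcomeric protein, rose from 1.71 ± 0.704 in psoas major to 16.5 ± 10.3 TPM in longissimus dorsi (log2 fold change 2.55, adjusted p = 0.000295), higher in 6 of 6 animals. GADL1 and PLPP4 did not pass as deposited (log2 differences 0.94 and 0.59) and did after scaling (1.68 and 1.09). MRPS6 was lower, at 1.23 ± 0.865 against 15.4 ± 10.8 TPM.

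**Figure D4:**
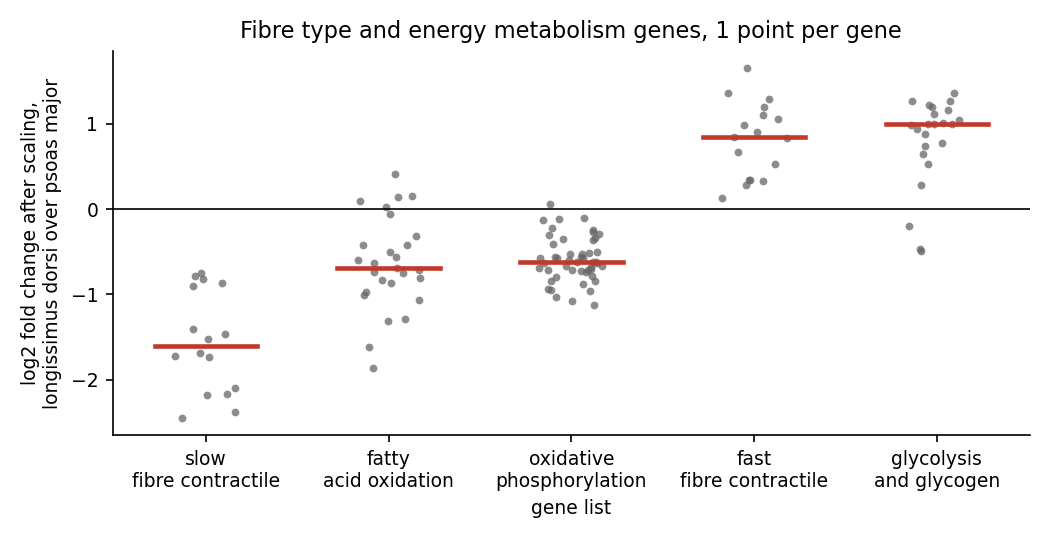
Log2 fold change after scaling, longissimus dorsi over psoas major (vertical axis), of the genes of 5 lists (horizontal axis). Points are genes and red lines are medians, which were -1.60 for slow fibre genes and 0.99 for glycolysis and glycogen genes. As deposited, the median of all genes was -0.45.

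Oxidative phosphorylation genes had a median of -1.34, with 0 of 49 past as deposited and 30 lower after scaling, when the median was -0.62 (camera adjusted p = 7.07e-07, adjusted p = 0.883 with an estimated correlation). Erythroid markers (2 of 3 lower, camera adjusted p = 5.71e-06, adjusted p = 0.336 with an estimated correlation) and endothelial markers (7 of 11 lower adjusted over the list alone, camera adjusted p = 0.000413, adjusted p = 0.778 with an estimated correlation) were lower in longissimus dorsi, as were lipid synthesis genes, 3 of 13 of which were lower, and interferon response genes (camera adjusted p = 0.00107 and 0.00824, adjusted p = 0.836 and adjusted p = 0.883 with an estimated correlation). Skeletal muscle markers (camera adjusted p = 5.71e-06), immediate early genes (0.000778), ribosomal proteins (0.000796), proteolysis genes (0.000796) and adipocyte markers (0.00123) were higher than other genes, with adjusted p = 0.745, 0.745, 0.908, 0.883 and 0.745 with an estimated correlation, and immediate early genes did not pass after scaling. For longissimus dorsi against psoas major, 138 of 8147 genes tested changed, 4 higher and 134 lower, and after scaling 1170 changed, 615 higher and 555 lower, with 117 called both ways. The count was 31 without transgenic 1, 60 without transgenic 2, 27 without wild-type 1, 35 without wild-type 2 and 465 without wild-type 3, and 0 with no filter on low values and 89 with a pseudocount of 0.1 TPM. In the simulation this fit as deposited called 13 unchanged genes and recovered 17 of 89 genes changed by 4-fold. A part of the 138 may thus be false calls.

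Whether the genotype effect itself differed between the 2 muscles was tested on the differences within each animal. The effect on oxidative phosphorylation genes was higher in longissimus dorsi than in psoas major, with a median difference of 0.17, where all genes had -0.11, and 0.43 after scaling with all 49 genes positive (camera adjusted p = 1.68e-05, adjusted p = 0.895 with an estimated correlation). Effects on glycolysis genes (median -0.60, camera adjusted p = 1.74e-17), hepatocyte markers (1.55e-11), fast fibre genes (3.11e-11), skeletal muscle markers (1.48e-07), heat shock genes (3.04e-05), extracellular matrix genes (0.00402) and the follistatin, activin and myostatin genes (median -0.32, 0.0431) were lower in longissimus dorsi, and those on interferon response genes (0.0112) and erythroid markers (0.0261) higher. All had adjusted p = 0.895 with an estimated correlation, and after scaling 5 lists passed where 10 had, among them those of oxidative phosphorylation, hepatocyte, heat shock and follistatin genes. Limma called 0 of 8147 genes, as deposited and after scaling, with 17 and 604 genes at an unadjusted p under 0.05. ARG2, APOB, NFIL3 and HBA2 had separate groups without passing, with log2 differences of -1.39, -1.05, -1.07 and 1.03 (adjusted p = 1). The count was 1 without wild-type 3.

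The 2 fat depots were compared within the 6 animals to ask how a subcutaneous and an internal depot differ. A homeobox gene, a T-box gene and genes of the matrix were among those that separated them. HOXA9 (ENSSSCG00000028997), a positional homeobox gene, was at 0.0817 ± 0.111 TPM in subcutaneous and 5.02 ± 2.31 TPM in retroperitoneal fat (n = 6 libraries each, log2 fold change -2.40, SE 0.256, adjusted p = 7.38e-18, and 0.000102 after scaling), and TBX15, a T-box gene of subcutaneous fat, at 13.8 ± 7.16 against 1.47 ± 0.662 TPM (adjusted p = 1.58e-11), each in the same direction in 6 of 6 animals. CBR2 was at 0.132 ± 0.122 against 10.7 ± 7.99 TPM, MATN4, a matrix protein, at 0.808 ± 0.444 against 18.2 ± 13.2 TPM, and PGR, the progesterone receptor, at 0.605 ± 0.486 against 6.11 ± 2.42 TPM. SCD, stearoyl-CoA desaturase, was higher in subcutaneous fat, at 137.3 ± 276 against 3.88 ± 2.65 TPM, as were PIK3C2G, at 9.45 ± 5.38 against 1.37 ± 1.34 TPM, SPP1, at 14.3 ± 16.0 against 1.31 ± 0.828 TPM, and LEP, the adipocyte hormone leptin, at 5.23 ± 4.74 against 1.44 ± 1.05 TPM. CBR1, higher by log2 2.17, shares its symbol and is uncertain. SPP1, LEP and CBR1 did not pass after scaling (adjusted p = 0.0583, 0.12 and 0.153).

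Extracellular matrix genes were higher in subcutaneous fat, 7 of 32 over all genes and 13 adjusted over the list alone, with a median of 0.66, or 0.83 after scaling (camera adjusted p = 5e-15, adjusted p = 0.646 with an estimated correlation). POSTN, periostin, was at 727.7 ± 756 against 139.5 ± 127 TPM, FN1, fibronectin, at 241.8 ± 171 against 72.4 ± 49.5 TPM, COL12A1 at 61.3 ± 28.0 against 14.8 ± 18.2 TPM and COL1A1 at 285.7 ± 219 against 132.8 ± 161 TPM. After scaling 5 of the list passed, and COL1A1 did not (adjusted p = 0.0935). The fibroblast genes PI16, DPT and MFAP5 were lower, with log2 fold changes of -2.15, -1.87 and -1.82, and PI16 did not pass after scaling (adjusted p = 0.0505). Adipocyte identity genes (median -0.55, camera adjusted p = 0.0218), lipolysis genes (0.0218), ribosomal proteins (0.0218), heat shock genes (0.00103), immediate early genes (0.00345) and T and NK cell markers (0.0096) were lower in subcutaneous fat, with adjusted p = 0.893 with an estimated correlation, as were erythroid markers (0.0096, adjusted p = 0.83 with an estimated correlation), and lipid synthesis genes were higher (0.0173, adjusted p = 0.893 with an estimated correlation). The T and NK cell, erythroid and lipid synthesis lists did not pass after scaling. Skeletal muscle markers rose in 11 of 13 (camera adjusted p = 3.79e-46, adjusted p = 0.0749 with an estimated correlation), keratinocyte markers in 4 of 4 and neutrophil markers in 2 of 4 (adjusted p = 0.0608 for both with an estimated correlation), and hepatocyte and mesothelial markers were higher (camera adjusted p = 3.97e-09 and 0.00103, adjusted p = 0.646 and adjusted p = 0.518 with an estimated correlation). After scaling 0 members of these 5 lists passed and the neutrophil, hepatocyte and mesothelial lists no longer did, and ACTA1 was highest in wild-type subcutaneous fat 2, at 1049 TPM, and KRT5 in transgenic subcutaneous fat 2, at 73.6 TPM. For subcutaneous fat against retroperitoneal fat, 284 of 12851 genes tested changed, 218 higher and 66 lower, and after scaling 570 changed, 220 higher and 350 lower, with 87 called both ways (48 higher and 39 lower). The count was 124 without transgenic 2, 500 without transgenic 3, 141 without wild-type 2 and 186 without wild-type 3, and 6 with no filter on low values. In the simulation this fit called 119 unchanged genes as deposited and 9 after scaling. Many of the 284 may thus be false calls.

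The genotype effect was also compared between the 2 fat depots within each animal. It was lower in subcutaneous than in retroperitoneal fat for genes of hepatocytes, of which 13 of 14 passed, all 14 adjusted over the list alone, with a median difference of -3.21, or -2.61 after scaling (camera adjusted p = 1.06e-58, adjusted p = 0.137 with an estimated correlation). ALB had a log2 difference of -4.61 (SE 0.622, adjusted p = 8.65e-10), and BHMT, AHSG, FGA, APOA2 and ORM1 ones of -3.81, -3.69, -3.22, -3.21 and -3.11, of which FGA is uncertain since it shares its symbol. None of them passed after scaling (adjusted p = 1), in a fit that recovered 0% of simulated 4-fold changes. Single libraries held much of the difference in ALB. It was at 1433 TPM in wild-type subcutaneous fat 2 and at most 111.4 TPM in the other subcutaneous libraries. In retroperitoneal fat it was at 534.0 and 251.1 TPM in transgenic 1 and 2, and at most 72.1 TPM in the others. The SE of 0.622 was set by the trend over genes and does not measure this spread. Of 14 macrophage markers LAPTM5 and CD68, which is uncertain since it shares its symbol, passed with differences of -1.98 and -1.81, and 13 adjusted over the list alone (camera adjusted p = 1.99e-08). Immediate early genes (8 of 21 adjusted over the list alone, 2.75e-05), adipocyte identity (8 of 19, 0.00047), oxidative phosphorylation (0.000302), interferon response (0.00105), fatty acid oxidation (0.00513), endothelial markers (0.0182), cholesterol synthesis (0.0292) and extracellular matrix genes (11 of 32, 0.0444) were lower as well, and these and the macrophage markers had adjusted p = 0.888 with an estimated correlation. Keratinocyte markers (2.1e-10), mesothelial markers (2.18e-10) and Schwann cell markers (0.03) were higher, with adjusted p = 0.24, 0.137 and 0.888 with an estimated correlation, and the Schwann cell list did not pass after scaling. Adjusted over the list alone 1 macrophage marker was lower after scaling, and 0 hepatocyte, immediate early, adipocyte identity and extracellular matrix genes were.

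Of 12851 genes 126 differed between the depots in their genotype effect, 2 higher and 124 lower, where the median of all genes was -0.77, and after scaling limma called 0, with 509 at an unadjusted p under 0.05. THEM4, NXPE2 and PRR15L had higher effects in subcutaneous fat without passing, with log2 differences of 1.43, 1.65 and 1.14. The count was 33 without transgenic 1, 25 without transgenic 2, 49 without wild-type 1 and 82 without wild-type 2, and 0 with no filter on low values. In the simulation this fit as deposited called 21 unchanged genes and recovered 5 of 97 genes changed by 4-fold. Many of the 126 may thus be false calls.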

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

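Of the tests below, the one on the library scale was chosen after the result was seen, and its rule was made stricter after its value was known. A difference between the 2 fat depots in the genotype effect singled out 126 genes, and among those named BHMT (-3.813), AHSG (-3.687), FGA (-3.217), APOA2 (-3.21) and ORM1 (-3.108), each given as the log2 difference of the effect in subcutaneous minus retroperitoneal fat. Limma called 124 of the 126 lower in subcutaneous fat.

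Of the 124 lower genes 73 (58.9%) are liver-enriched, against 220 (1.73%) of the other genes tested. RNA from liver in some fat samples could account for these: over 77 genes abundant in liver and low in fat, 100% of the levels in wild-type subcutaneous fat 2 lay within 4-fold of the median share of 5.12% of the liver level, and ALB was at 1433 TPM there. In every fat library at least 77.9% of the 77 genes lay within 4-fold of the library's own median share. This test thus does not single out wild-type subcutaneous fat 2, which differs in the size of its share. The median share was 1.44% in transgenic retroperitoneal fat 1 and at most 0.659% in the other 10 libraries. The libraries with most liver transcripts are thus of opposite genotype in the 2 depots, and the source of the transcripts was not tested. The library scale cannot be told apart from an effect in these genes: after scaling the median difference was -1.72 (median SE of single genes 0.78), from -2.37 (0.54) before, and -1.24 for the 51 genes that are not liver-enriched, where the median of all genes went from -0.77 to 0.001, but the genes were chosen for being low. No gene was called after scaling, where differences were smaller and errors larger. The errors before scaling were set by the trend over genes and left out each gene's own spread between animals. The 2 errors are thus not like measures. The lack of calls decides nothing, since the scaled fit recovered 0% of simulated 4-fold changes. The rule's demand for calls could thus hardly be met, and a genotype effect that differs between the depots stays open as untested.

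For this count the 10 splits of the 6 animals are too few for a share under 0.05: the real split gave 126 genes, 1 split gave as many, which is the real one, and the highest other gave 34.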

How the results depend on the processing

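The size of the libraries limits these results, since the totals of a tissue differ by up to 6.34-fold and read depth was not used here, and so does the filter on low values, without which 53 named genes lost the threshold, against 35 with scaling. Of 1186 combinations of a named gene and an alternative setting 912 kept their direction and side of the threshold, 207 lost the threshold, 66 gained it and 1 reversed, FBLN1 in longissimus dorsi at -0.137 with scaling and without transgenic 2. The cause was not tested for the changed results below, except that leaving out libraries leaves fewer animals and dropping the filter adds genes with low values to the test. List tests were not rerun without each library.

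Counts of called genes are given against 117 in liver, 8 in longissimus dorsi, 3 in psoas major, 0 in subcutaneous fat, 80 in retroperitoneal fat, 1 for the mean over tissues, 0 and 126 for the genotype effect in longissimus dorsi minus psoas major and in subcutaneous fat minus retroperitoneal fat (the differences between the muscles and between the depots), 138 for longissimus dorsi against psoas major and 284 for subcutaneous fat against retroperitoneal fat. Median-of-ratios scaling gave 39 in liver, 3 in longissimus dorsi, 1 in retroperitoneal fat, 0 for the difference of effects between the depots, 1170 between the muscles and 570 between the depots. With no filter on low values they were 23 in liver, 0 in longissimus dorsi, 0 in psoas major, 3 in retroperitoneal fat, 0 between the muscles, 6 between the depots and 0 for the difference between the depots. A pseudocount of 0.1 TPM gave 7 in subcutaneous fat, 3 for the mean over tissues and 89 between the muscles. All 30 libraries in 1 fit gave 63 in liver, 2 in longissimus dorsi, 36 in subcutaneous fat and 559 in retroperitoneal fat. These settings kept the other counts within 1.5 times.

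Leaving out each library in turn gave 33 to 941 genes in liver (319 without wild-type 1, 33 without wild-type 2, 941 without wild-type 3), 0 to 5725 in longissimus dorsi (4, 5725 and 1 without transgenic 1, 2 and 3, and 0 without each wild-type), 0 to 22 in psoas major (0 without transgenic 1, transgenic 2 or wild-type 2, 14 without wild-type 1, 22 without wild-type 3), 0 to 294 in subcutaneous fat (294 without transgenic 1, 6 without transgenic 3, 1, 23 and 2 without wild-type 1, 2 and 3) and 3 to 1305 in retroperitoneal fat (1305, 190 and 262 without transgenic 1, 2 and 3, and 3, 164 and 319 without wild-type 1, 2 and 3). It gave 1 to 13 for the mean over tissues (2 and 4 without transgenic 1 and 3, and 13, 2 and 3 without wild-type 1, 2 and 3), 0 to 1 for the difference between the muscles (1 without wild-type 3), 27 to 465 for longissimus dorsi against psoas major (31 and 60 without transgenic 1 and 2, and 27, 35 and 465 without wild-type 1, 2 and 3), 25 to 128 for subcutaneous fat minus retroperitoneal fat (33 and 25 without transgenic 1 and 2, 49 and 82 without wild-type 1 and 2) and 124 to 500 for subcutaneous fat against retroperitoneal fat (124 and 500 without transgenic 2 and 3, 141 and 186 without wild-type 2 and 3).

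Alternatives added after seeing the data were scaling together with leaving out 1 library, which gave 32 genes in liver without wild-type 2, 1 in psoas major without wild-type 3, 1 in retroperitoneal fat without transgenic 1 and 0 for the difference between the depots without wild-type 2, and a variance trend on the expression level, which gave 1 gene for the difference between the muscles and 264 for subcutaneous fat minus retroperitoneal fat. Lists past the threshold numbered 5 against 8 in liver with no filter, 10 against 19 in subcutaneous fat with scaling and without wild-type 2, 8 against 15 in retroperitoneal fat with scaling and without transgenic 1, and 5 against 10 for the difference between the muscles with scaling.

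Leaving out libraries for FST was added after seeing the data. The FST difference in longissimus dorsi was -0.058 after scaling and ranged from -0.097 to 0.334 with a library left out, being -0.030 without transgenic 1, -0.097 without transgenic 3 and -0.020 without wild-type 2. In retroperitoneal fat it was -0.217 after scaling and ranged from -0.128 (without wild-type 1) to 0.934, and in liver it ranged from -1.019 to 0.053 (without wild-type 2).

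The animals of the genotypes share only replicate numbers. In no tissue was the correlation of every same-numbered pair above 0.1, and 1 to 4 of 6 libraries correlated best with their own number. With the replicate block the counts were 401 in liver, 0 in longissimus dorsi, 54 in psoas major, 183 in subcutaneous fat, 5969 in retroperitoneal fat and 197 for subcutaneous fat minus retroperitoneal fat. The tissues were compared with the animal as the block, and without it subcutaneous and retroperitoneal fat differed in 12 genes. Adding or removing a block moved no other count by over 1.5 times.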

Other observations

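Of the tests below, those on the library scale and on the UQCRH reads were chosen after the results were seen. The genes MT-ATP8 and MT-ND1, encoded by mitochondrial DNA, separated transgenic 1 and 2 from transgenic 3. MT-ATP8 was at 21.9 TPM or above in transgenic 1 and 2 in liver, at 87.7 and 6.43 TPM in longissimus dorsi, at 280.5 and 152.5 TPM in psoas major, at 68.4 and 256.6 TPM in subcutaneous fat and at 48.4 and 160.8 TPM in retroperitoneal fat, and at most 1.28 TPM in every library of transgenic 3 and of the wild-type animals. Of 2 genes with the symbol MT-ND1, ENSSSCG00000035520 was at most 2.18 TPM in the libraries of transgenic 1 and 2, and between 7.48 and 21.4 TPM in those of transgenic 3. The other, ENSSSCG00000018065, was at 124.7 and 86.3 TPM in psoas major of transgenic 1 and 2 and at 4.06 TPM in that of transgenic 3. These values were picked after they were seen, and no explanation was tested.

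Small amounts of muscle RNA in the transgenic livers could account for the higher skeletal muscle transcripts there: over 42 genes abundant in muscle and low in wild-type liver, 97.6% of the differences between the genotypes lay within 4-fold of the median share of 0.276% of the muscle level. All 42 differences were positive and in 41 genes every transgenic liver lay above every wild-type one, without a test of each gene. The genes were chosen for being low in wild-type liver alone, which favours positive differences. The median level was 0.342%, 0.346% and 0.299% of the muscle level in the transgenic livers and 0.0564%, 0.0512% and 0.0457% in the wild-type livers. The library scale is argued against, since the marker list's median log2 fold change was 1.52 after scaling, and carry-over of tissue and exchange of reads between libraries sequenced together were not tested against each other, and a genotype effect on these genes in liver stays open as untested.

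The UQCRH gene ENSSSCG00000035894 was near 0 in wild-type and present in transgenic libraries. Reads shared with the other UQCRH gene, ENSSSCG00000003903, are a candidate explanation. In 14 of 15 transgenic libraries the level lay within 4-fold of the median ratio of 9.66% to that gene, with a range from 0.683% to 18.2%. The highest wild-type ratio was 1.2%. A steady ratio within the transgenic libraries cannot tell shared reads from a separately expressed copy of the gene, so it does not decide between them. After scaling 15 of 15 transgenic libraries lay above the highest wild-type library of their tissue. In both fat depots this was fixed in advance, since scaling cannot move wild-type values of 0. In liver, longissimus dorsi and psoas major the library scale is argued against. The lowest transgenic levels there were 4.22, 4.73 and 10.4 after scaling, and the highest wild-type ones 0.369, 0.353 and 2.49. Which sequence difference between the animals would divide the reads this way was not tested, and a copy of the gene that is expressed in the transgenic animals alone, or another genotype effect, stays open as untested.

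Other splits of the 6 animals into 3 and 3 were counted for each comparison of genotypes, and 10 splits are too few for a share under 0.05. The numbers of splits that gave as many genes as the real one, which is included, were 1 in liver (real 117, highest other 90), 4 in longissimus dorsi (8 and 19), 6 in psoas major (3 and 5798), 10 in subcutaneous fat (0 and 2594), 3 in retroperitoneal fat (80 and 243), 1 for the mean over tissues (1 and 0) and 10 for the difference of effects between the muscles (0 and 5332). The splits with 5798, 2594 and 5332 genes put transgenic 1, transgenic 2 and wild-type 1, transgenic 1, transgenic 3 and wild-type 2, and transgenic 1, transgenic 3 and wild-type 3 together. They follow the library scale and not the genotype. The median ratios used for scaling were 1.66, 1.35 and 1.91 against 0.761, 1.04 and 0.305 in psoas major. In subcutaneous fat they were 0.782, 0.669 and 0.933 against 1.37, 1.33 and 1.09. The last split holds the animals whose ratio was higher in longissimus dorsi than in psoas major. After scaling the highest other splits gave 1, 0 and 0 genes. After scaling the real split gave 39 genes in liver and the highest other 1, and in longissimus dorsi the real split gave 3 genes and another split, of transgenic 1, wild-type 1 and wild-type 2, gave 4. The scaled counts of the real and the highest other split were 2 and 1 in psoas major, 1 and 0 in retroperitoneal fat and for the mean over tissues, and 0 and 0 in subcutaneous fat. For the tissues compared within animals, 3 of 32 ways of swapping the muscles gave as many genes as the real 138 and the highest other gave 7025, and 2 of 32 ways of swapping the fat depots gave as many as the real 284 and the highest other gave 2098, so chance cannot be excluded as deposited. After scaling the real counts were 1170 and 570 and the highest others 0 and 76.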
